A study of Arabidopsis thaliana with 3 samples.

How the data were processed

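Small RNA libraries from Arabidopsis inflorescences were analysed, 1 each from total RNA, AGO1 complexes and AGO10 complexes, with groups taken from the labels. The deposited values are read counts per distinct small RNA sequence, per the file headers. Sequences were 19 to 28 nt long and carried no adapter. The genome build was TAIR10, per the submitters' processing notes. The adapter trimmer, the aligner and the read filters are not given in the sources used here. The labels state no library totals, so the listed reads serve as depth, and they are not the full depth of sequencing. The counts were treated as raw because they are whole numbers with different sums, 3805243 for total RNA, 2060961 for AGO1 and 4043906 for AGO10.

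Each listing also held 291 names of miRNA hairpins without a count, which were left out. All listed sequences were matched to the TAIR10.1 genome with bwa 0.7.19, allowing no mismatch or gap and keeping every position, and 0 reads were unmatched. The coordinates are those of TAIR10.1, 1-based. Hairpin-derived sequences kept their own orientation. Other sequences were nearly all listed as the genome minus strand: 71.7% of distinct sequences in total RNA, 71.5% in AGO1 and 69.2% in AGO10 matched the minus strand alone, and 0.131%, 0.273% and 0.281% the plus strand alone. Most sequences matching both strands stood in both orientations. Among sequences whose reverse complement was also listed, the counts of the pair were equal in 99.9%, 100.0% and 100.0%. Such a pair was counted once, which left 3325949, 1893341 and 3849586 reads. A sequence read from both strands stood on 2 lines whose counts always differed, so reads seen equally often from both strands may be undercounted. The strand of non-hairpin reads and their first base were therefore not analysed. This limited the first-base comparison to hairpin reads, against the wider plan.

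Single-match sequences outside hairpins stopped at nearly the same place in all 3 libraries. They covered chromosome 1 up to 21.4 Mb, chromosome 2 up to 11.3 Mb, chromosome 4 up to 12.5 Mb and chromosome 5 up to 17.7 Mb, all of chromosome 3, and no organelle genome, or 72.4% of the nuclear genome. Covered ends were set at the last match before a gap over 1000000 bp. Reads of the remaining part were not analysed here unless they came from hairpins or also matched the covered part. The missing reads are non-hairpin reads, whose share differs between libraries, so the totals used for RPM are reduced unequally and ratios between libraries are shifted, those against total RNA most. Ratios relative to guide reads are free of this. The shares of miRNA reads are higher than they would be over the whole genome.

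Entries were the first 18 nt of 91 sequences listed before the data were examined: 63 guide, 17 star and 3 ta-siRNA entries. An entry held all reads of up to 25 nt with its prefix, so family members that share the prefix were counted together. The ta-siRNA entries were looked up in both orientations. Levels are RPM of the reads counted once. Ratios have exact conditional binomial 95% intervals and shares have Clopper-Pearson 95% intervals. All intervals cover counting error only. A library with 0 reads was set to 3 reads, per library, equal to 0.902 RPM in total RNA, 1.58 in AGO1 and 0.779 in AGO10. With 1 library per group no test was run. The deposited counts would suit a count model only with replicates. An entry was called higher or lower when either library had at least 100 reads, the ratio was at least 2-fold and its interval excluded equality. A list's median log2 ratio was placed among 10000 random lists of guide entries of the same size and level group, drawn with seed 7, as a description of these libraries. A 0 count entered such medians at its bound.

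Gene reads were split evenly over all matches, after reads matching a miRNA hairpin or structural RNA were set aside. Structural RNA held annotated ribosomal, transfer, small nuclear and small nucleolar RNA genes, organelle genomes, and 8000 bp from each nuclear 18S gene start. The last was added after it was seen that the 25S gene carries no rRNA annotation. Of the hairpins named in the deposited listings, 279 were found in the reference annotation, which has 326.

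The text names, by a rule set before the data were examined, both miR165 and miR166; the 10 highest and 10 lowest called entries of each comparison; the 5 most abundant entries and sequences of each library; each of the 15 listed loci with at least 100 reads; and the 5 highest and 5 lowest other genes by AGO10 to AGO1 ratio among those with at least 200 reads. The lists were conserved and less conserved guides, guides by first base, 22-nt guides, star strands, ta-siRNAs, TAS loci, HD-ZIP III genes, the AGO1 and AGO10 genes, and structural RNA. Alternatives covered 4 other scalings, full mature sequences, minimums of 20 reads and 1 read, distinct sequences, single-match or 21-nt TAS reads, and several choices added later. The split of other genes and the listed loci under each scaling, and the star share without miR165 and miR166, were added after the main values were seen.

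The counting of pairs once and the calling rule were tested on simulated data. With 20 entries changed 4-fold in 100 draws, the rule called 100% of changed entries and 0% of unchanged ones in all 3 comparisons, which ran on 46, 44 and 42 simulated entries. The intervals held the true ratio in 95.1% of cases for AGO10 against AGO1, 94.8% for AGO1 against total RNA and 95.5% for AGO10 against total RNA. These draws hold counting error alone, for entries expected to reach 100 reads in the smaller library. The simulated change lay well above the 2-fold limit, so the draws do not give the error rate of the calls made here. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 were used.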

Results

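Small RNAs of Arabidopsis thaliana (ecotype Col-0) inflorescences were sequenced from 3 sources: total RNA, purified complexes of the small RNA effector ARGONAUTE1 (AGO1), and purified complexes of its relative ARGONAUTE10 (AGO10). Both proteins carried a dual tag, were expressed from their own promoters in the matching mutant, and were isolated from floral buds, flowers and very young siliques in 2 affinity steps. Each source had 1 library, so no difference below has a replicate check and no p-value is given. Listed reads numbered 3805243 in total RNA, 2060961 in AGO1 and 4043906 in AGO10. After reads listed in both orientations were counted once, 3325949, 1893341 and 3849586 remained, and levels are given relative to these, as RPM. All intervals are exact 95% intervals that cover counting error only, because reads without molecular identifiers are not independent molecules.

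The first comparison asked which small RNAs AGO10 carried relative to AGO1, with miR165 and miR166 as the main item because the cited protocol study is about their recruitment by AGO10. These miRNAs direct repression of HD-ZIP III transcription factor mRNAs. MiR166 took 2185284 reads in the AGO10 library, 97205 in AGO1 and 16154 in total RNA, and was 11.1-fold higher in AGO10 than in AGO1 (interval 11 to 11.1). MiR165 was 5.54-fold higher (5.48 to 5.60), with 408299, 36244 and 3606 reads in the same order. Together they were 9.56-fold higher in AGO10 than in AGO1 (9.51 to 9.61). They were also the most abundant and the second most abundant of the guide miRNAs in AGO10.

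Both miRNAs made up 88.0% of the reads of the listed guide miRNAs in AGO10 (87.9% to 88.0%), 14.6% in AGO1 (14.6% to 14.7%) and 7.98% in total RNA (7.87% to 8.08%). As a share of all reads they took 67.4% of the AGO10 library, 7.05% of AGO1 and 0.594% of total RNA. The fold depended on the scaling. It was 42.8 when the libraries were scaled to guide miRNA reads without miR165 and miR166, and 21.3 under median-of-ratios scaling. The mature miR166 sequence TCGGACCAGGCTTCATTCCCC matched 7 places in the TAIR10.1 genome, 1 in each of the miRNA genes MIR166a to MIR166g, including chromosome 2 from 19176241 to 19176261 in MIR166a. The reads cannot be assigned among these genes. The miR165 sequence TCGGACCAGGCTTCATCCCCC matched MIR165a on chromosome 1 from 78932 to 78952 and MIR165b on chromosome 4 from 369856 to 369876. It differs from miR166 by U17C, counted from 1 at the 5′ end.

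Reads of 21 nt made up 96.4% of miR165 and miR166 reads in AGO10 (96.4% to 96.5%), 96.2% in AGO1 (96.1% to 96.3%) and 94.3% in total RNA (94.0% to 94.6%). The 20-nt forms took 2.38%, 2.37% and 3.94%, and the 22-nt forms 0.140%, 0.451% and 0.349%. Every listed sequence matched the genome, so untemplated 3′ tails were not analysed here. The listed star strands of both miRNAs, the passenger strands of their duplexes, were rare next to the guides in both complexes. These star strands match only MIR165a, MIR166a and MIR166b, while the guide reads may come from all the genes named above. Star strands of the other genes were not counted, so the star values are those of a part of the family. The listed star strands had 34 reads against 2593583 guide reads in AGO10 and 1 read against 133449 in AGO1. In total RNA they took 2.65% of listed star and guide reads of the family (2.43% to 2.88%).

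**Figure D1:**
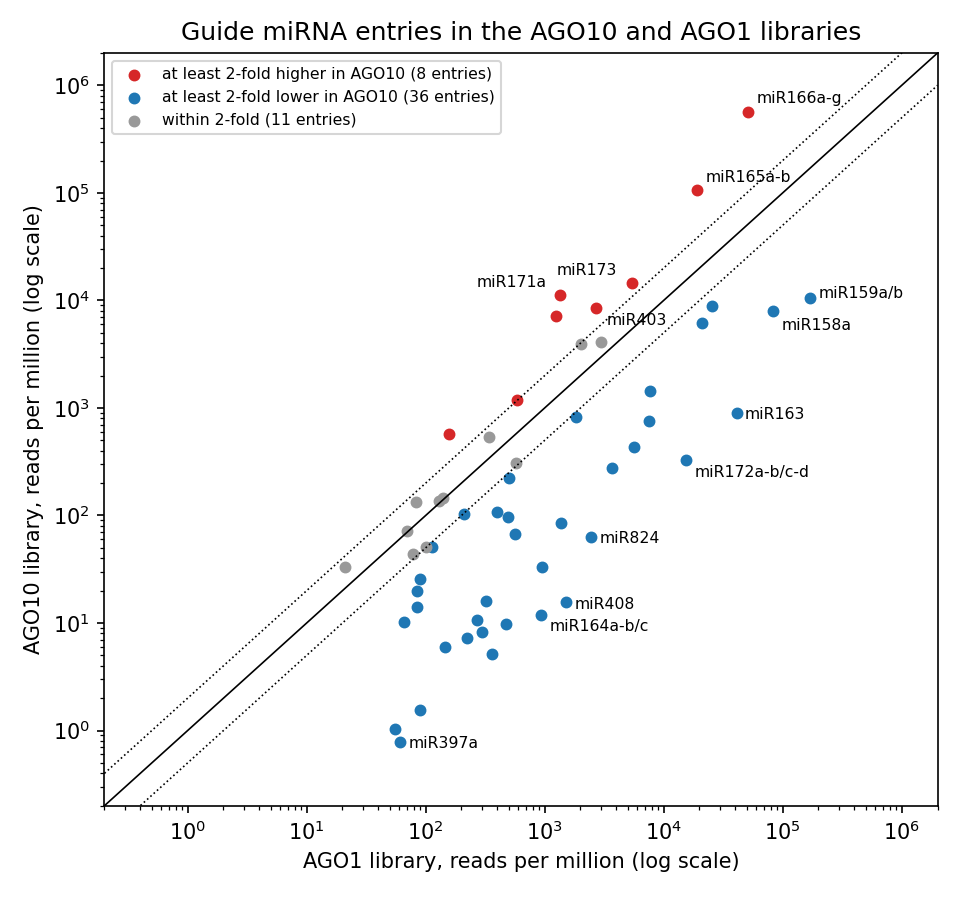
Levels of 55 guide miRNA entries in the AGO1 library (x axis) and the AGO10 library (y axis), in RPM on log scales. Each point is 1 entry, the solid line marks equal levels, dotted lines mark 2-fold differences, and 1 library stands behind each axis. The 8 entries higher in AGO10 include miR166 and miR165 at the top, and 36 entries are at least 2-fold lower in AGO10, a split that moves to 22 and 22 relative to guide reads without miR165 and miR166.

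Most other miRNAs were lower in AGO10 than in AGO1. Of 55 guide entries with at least 100 reads in either library, 8 were at least 2-fold higher in AGO10, 36 were at least 2-fold lower, and 11 were within 2-fold or had an interval that did not exclude equality. Besides miR166 and miR165, the higher entries were miR171a, miR171b and c, miR169a to c, miR403, miR173 and miR775. MiR171, which targets HAM transcription factor mRNAs, was 8.34-fold higher for the miR171a form (8.02 to 8.69) and 5.68-fold higher for the miR171b and c form (5.44 to 5.92). MiR169a to c, which target NF-YA mRNAs, were 3.66-fold higher (3.24 to 4.14). MiR403, which targets AGO2 mRNA, was 3.14-fold higher (3.05 to 3.23), and miR173, the trigger of TAS1 and TAS2 small interfering RNAs, was 2.66-fold higher (2.60 to 2.71). MiR775 was 2.01-fold higher (1.88 to 2.15).

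The lowest entries in AGO10 were headed by miR397a, a regulator of laccases, which had 116 reads in AGO1 and 1 in AGO10, a level 236-fold lower (41.5 to 9395). MiR408, another regulator of copper proteins, was 96.9-fold lower (75.0 to 127). MiR164, which targets NAC transcription factors, was 78.2-fold lower (58.4 to 107). The AP2 regulators miR172e and miR172a to d were 69.1-fold and 47.7-fold lower. MiR156, which targets SPL factors, was 47.8-fold lower, miR163 45.4-fold lower and miR824, which targets AGL16, 39.2-fold lower. MiR771 was 57.9-fold lower and miR2111 53.4-fold lower, on 6 and 4 reads in AGO10. Of these, miR397a, miR408 and miR2111 had too few reads for a call between AGO10 and total RNA. They had 1, 60 and 4 reads in AGO10 against 1, 63 and 6 in total RNA, so their low ratios go with high levels in AGO1. The others named up to here were also at least 2-fold lower in AGO10 than in total RNA. Abundant families differed too. MiR159, which targets GAMYB-like factors, was 16.0-fold lower in AGO10 (15.8 to 16.2) and miR158 was 10.5-fold lower (10.4 to 10.6). The miR159 fold pools unlike members. Exact miR159a stood at 1698 RPM in AGO10 and 115512 in AGO1, and miR159b at 7966 and 46665.

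The counts of higher and lower entries depended on the scaling, since reads of miR165 and miR166 filled most of the AGO10 library. With libraries scaled to the other guide reads, 22 entries were higher and 22 lower, and with median-of-ratios scaling 16 were higher and 27 lower. The median log2 ratio over the 55 entries was -2.08 in the main scaling, 0.08 in the former and -0.93 in the latter. The 8 higher entries were higher under every one of the 5 scalings, the main one included, and 22 of the 36 lower entries were lower under every one. These 22 hold each of the lower entries named so far. Direction flipped for 12 entries, miR319, miR396, miR162 and miR395 among them. MiR319 and miR396 did not flip under median-of-ratios scaling. The scaling to other guide reads rests largely on miR159 and miR158, which were themselves lower in AGO10 and add to its shift. They held 320612 and 156825 of the 779168 other guide reads in AGO1, against 40721 and 30409 of 354189 in AGO10. The miR396 flip is that of a pooled entry. Exact miR396a stood at 3143 RPM in AGO10 and 2795 in AGO1, and miR396b at 838 and 13678.5.

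Lists of miRNAs fixed before the data were examined did not stand far apart from random lists of guide entries of matched level. Of the 33 measured conserved guides other than miR165 and miR166, 4 were higher in AGO10 than in AGO1 and 23 were lower, with a median 3.69-fold lower level, at percentile 65.8 of 10000 random lists. Of 20 less conserved guides, 2 were higher and 13 lower, with a median 6.26-fold lower (percentile 23.3). Of 45 other guides with 5′ U, 5 were higher and 29 lower, with a median 4.22-fold lower (percentile 39.1). Of 8 guides with another 5′ base, 1 was higher and 7 were lower, with a median 11.9-fold lower (percentile 30.5). Of 6 guides of 22 nt, 1 was higher and 3 were lower, with a median 3.58-fold lower (percentile 49.2).

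The second comparison asked which miRNAs AGO1 held relative to total RNA. The listed guides took 48.2% of AGO1 reads (48.1% to 48.3%) against 7.45% of total RNA (7.42% to 7.48%). Of 54 entries, 49 were at least 2-fold higher in AGO1, 0 were lower and 5 were within 2-fold or had an interval reaching equality. The largest folds belonged to miRNAs with few reads in total RNA. MiR397a had 116 reads in AGO1 and 1 in total RNA (204-fold, 35.9 to 8117), and miR397b had 423 and 6 (124-fold, 56.4 to 339). MiR408 was 79.7-fold higher (62.1 to 104) and the miR399a entry, of a family that targets the phosphate regulator PHO2, was 56.7-fold higher (34.6 to 99.9). That entry held 516 reads in AGO1 and 16 in total RNA, of which 69 and 5 were the exact miR399a sequence. The copper-responsive miR398 followed at 55.9-fold, miR2111 at 30.7-fold, miR827 at 21.4-fold and miR395b, c and f, regulators of sulfate assimilation, at 17.8-fold. MiR165 was 17.7-fold higher (17.1 to 18.3), miR160, which targets ARF mRNAs, 16.5-fold, and miR166 10.6-fold (10.4 to 10.7).

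The entries without a 2-fold difference were miR390, the trigger of TAS3 that is bound mainly by AGO7, together with miR394, miR170, miR391 and miR169a to c. The AGO1 level of miR390 was 0.720 of that in total RNA. Since miRNAs as a class took more of the AGO1 library, the split changed with the scaling. Relative to guide reads without miR165 and miR166, 13 entries were higher in AGO1 and 17 lower, and with median-of-ratios scaling 18 were higher and 4 lower. The median log2 ratio of the 54 entries went from 2.05 to -0.54 and 0.27, and the direction flipped for 34 entries. The 13 entries higher under every scaling were the named ones from miR397a to miR160, miR165 among them, together with miR395a, d and e, miR159 and miR399b and c. MiR166 was 1.76-fold higher relative to the other guide reads.

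Conserved guides other than miR165 and miR166 were higher in AGO1 for 28 of 32 measured entries, with 0 lower and a median 5.38-fold higher, at percentile 98.6 of the random lists. Less conserved guides were higher for 19 of 20, with a median 3.44-fold higher (percentile 16.1). Other guides with 5′ U were higher for 41 of 44 (median 3.8-fold, percentile 4.45), and guides with another 5′ base for 6 of 8 (median 9.07-fold, percentile 92.9). All 6 measured 22-nt guides were higher (median 4.14-fold, percentile 53.9).

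The third comparison set AGO10 against total RNA. MiR166 was 117-fold higher in AGO10 (115 to 119) and miR165 97.8-fold higher (94.7 to 101). Of 47 entries, 21 were at least 2-fold higher, 18 lower and 8 within 2-fold or with an interval reaching equality. After miR166 and miR165 came miR171b and c (34.3-fold, 31.8 to 37.0), miR398 (28.4-fold, on 6 reads in total RNA), miR160 (22.7-fold, 20.9 to 24.6), miR171a (17.0-fold, 16.3 to 17.8), miR173 (11.3-fold, 11 to 11.7), miR403 (8.84-fold, 8.52 to 9.17), miR395b, c and f (8.06-fold) and miR395a, d and e (7.76-fold).

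MiRNAs lower in AGO10 than in total RNA included miR771 (21.6-fold), miR164 (18.3-fold, 13.6 to 25.2), miR824 (17.1-fold, 15 to 19.5), miR156 (16.1-fold, 11.6 to 23.0) and miR157 (15.7-fold, 10.9 to 23.2). MiR172e (10.0-fold), miR172a to d (8.26-fold), miR447 (7.85-fold), miR390 (6.97-fold, 6.24 to 7.80) and miR163 (6.38-fold, 6.15 to 6.61) followed. Under every scaling, 18 of the 21 entries were higher and 16 of the 18 lower. The 20 entries named in this comparison are all among these.

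Of 28 measured conserved guides other than miR165 and miR166, 13 were higher in AGO10 than in total RNA and 8 lower (median 1.69-fold higher, percentile 69.3). Of 17 less conserved guides, 6 were higher and 10 lower (median 2.23-fold lower, percentile 5.34). Other guides with 5′ U were higher for 16 and lower for 14 of 38 (median 1.38-fold higher, percentile 40.1), guides with another 5′ base for 3 and 4 of 7 (median 2.36-fold lower, percentile 16.0), and 22-nt guides for 3 and 2 of 6 (median 1.63-fold higher, percentile 55.9). Another scaling moves all entries of a comparison alike and so changes these splits but not the order of the lists.

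The most abundant guide in total RNA was miR158 with 68140 reads, followed by miR159, miR319, miR163 and miR396. In AGO1 the order was miR159 with 320612 reads, then miR158, miR166, miR163 and miR319. In AGO10 miR166 and miR165 were followed by miR173 with 55492 reads, miR171a with 43042 and miR159 with 40721. The leading single sequence of total RNA was the 20-nt miR158a, TCCCAAATGTAGACAAAGCA, which matched MIR158a on chromosome 3 from 3366349 to 3366368 and took 1.89% of reads. In AGO1 the leader was miR159a, TTTGGATTGAAGGGAGCTCTA, in MIR159a on chromosome 1 from 27713234 to 27713254, with 11.6% of reads (11.5% to 11.6%). In AGO10 the 21-nt miR166 sequence alone took 54.7% (54.7% to 54.8%). The other leading sequences of the 3 libraries were the mature forms of miR319a and b, miR163, miR159b, miR165, miR173 and miR171a and the 20-nt form of miR166.

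**Figure D2:**
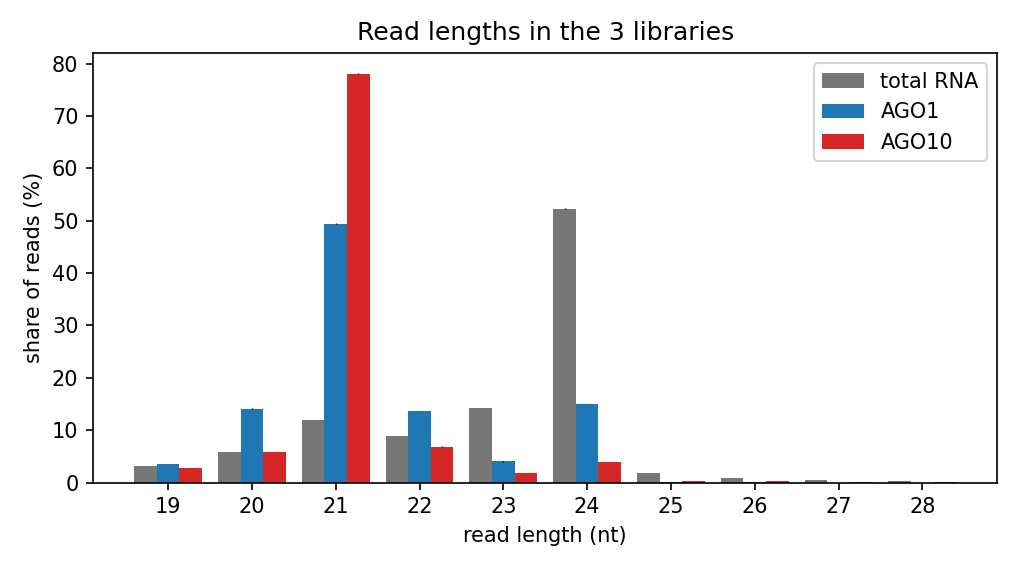
Share of reads (y axis, percent) at each length from 19 to 28 nt (x axis) in the total RNA, AGO1 and AGO10 libraries, 1 library each, with exact 95% counting intervals as error bars that are mostly too small to see. The 24-nt class leads in total RNA at 52.3%, and the 21-nt class leads in AGO1 at 49.4% and in AGO10 at 78.1%.

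Length classes separated the libraries. Reads of 24 nt, the usual length of heterochromatic small interfering RNAs, took 52.3% of total RNA (52.2% to 52.4%), 15% of AGO1 (15% to 15.1%) and 3.89% of AGO10 (3.87% to 3.91%). Reads of 21 nt took 12% (12% to 12%), 49.4% (49.4% to 49.5%) and 78.1% (78.0% to 78.1%). Outside miRNA hairpins the 21-nt class took 7.66%, 29.9% and 36.3%, and the 24-nt class 56.8%, 23.7% and 17.6%. Counted once per distinct sequence, 21-nt reads made up 24.3% in AGO10 and 23.9% in AGO1.

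Annotated miRNA hairpins took 9.14% of total RNA reads, 53.0% of AGO1 and 78.5% of AGO10. Structural RNA, meaning ribosomal, transfer and small nuclear or nucleolar RNA, is a marker of background fragments. It took 13.1% of total RNA (13.1% to 13.2%), 1.45% of AGO1 (1.43% to 1.47%) and 2.54% of AGO10 (2.53% to 2.56%). The order of the complexes rested on ribosomal spacer and 25S sequence without an rRNA annotation. With annotated structural genes alone the shares were 6.74%, 0.944% and 0.908%.

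First bases could be read only for hairpin-derived miRNA reads, because other sequences were nearly all written as the minus strand. Among 21-nt hairpin reads, 5′ U, the base associated with AGO1 loading, took 85.5% in total RNA (85.3% to 85.6%), 93.9% in AGO1 (93.8% to 93.9%) and 99.5% in AGO10 (99.5% to 99.5%). Without miR165 and miR166 the shares were 83.6% (83.4% to 83.8%), 92.4% (92.3% to 92.5%) and 93.7% (93.6% to 93.8%). At 22 nt the order was the same, with 89.3%, 93.6% and 97.6%. At 20 nt, AGO10 had the lowest 5′ U share, 89.0% against 95.2% in AGO1 and 95.8% in total RNA, and at 24 nt AGO10 had 97.7% against 99.7% in AGO1 and 89.3% in total RNA.

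Star strands took a smaller share of star and guide reads in the complexes than in total RNA. Over the families with a listed star strand, star reads made up 3.41% of star and guide reads in total RNA (3.33% to 3.49%), 0.497% in AGO1 (0.481% to 0.513%) and 0.0777% in AGO10 (0.0745% to 0.0810%). All listed guides of a family were counted, but star strands were listed for only some of its genes. The shares therefore also depend on guides whose star strand was not counted. Reads of miR165 and miR166 guides fill most of the AGO10 total. Without that family the shares were 3.50%, 0.607% (0.588% to 0.627%) and 1.08% (1.04% to 1.13%), so the order of AGO1 and AGO10 was the reverse. Summed star reads were at 0.294 of the AGO1 level in AGO10 (0.278 to 0.310), and at 0.169 without miR171a*, which held most star reads in both complexes. Relative to guide reads without miR165 and miR166 the direction of the full sum flipped, to 1.31, but under median-of-ratios scaling it stayed lower, at 0.653. Of 5 star strands with enough reads, 4 were lower in AGO10 than in AGO1 and 1, that of miR168, was 2.57-fold higher (1.85 to 3.65). Relative to guide reads without miR165 and miR166, those of miR171a and miR393 flipped to 1.65 and 1.47, while those of miR396 and miR408 stayed lower. Under median-of-ratios scaling, which multiplies these ratios by 2.22, all 4 stayed lower. The median of the 5 was 3.03-fold lower in the main scaling (percentile 69.8). Against total RNA, 7 of 10 measured star strands were lower in AGO1 and 2, those of miR171a and miR408, were higher. In AGO10, 8 of 9 were lower and 1, that of miR171a, was higher. Both medians lay at percentile 0 of the random lists, at 6.16-fold and 16.1-fold lower. MiR408* had 703 reads in AGO1, 1 in total RNA and 0 in AGO10. With the 0 set to 3 reads it was 476-fold lower in AGO10 than in AGO1, and the lower interval bound was 386-fold.

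Among trans-acting small interfering RNA (ta-siRNA) loci in the part of the genome covered by single-match reads, which are TAS1B, TAS3A and TAS4, most reads came from TAS3A, whose products target ARF3 and ARF4 mRNAs. Reads of the TAS3A gene, AT3G17185 on chromosome 3 from 5861491 to 5862437, stood at 30272 RPM in AGO10, 15652 in AGO1 and 4231 in total RNA, 1.93-fold higher in AGO10 than in AGO1 (1.91 to 1.96). That fold was 8.65 relative to guide reads without miR165 and miR166 and 4.30 under median-of-ratios scaling. TAS1B, AT1G50055, was 4.63-fold lower in AGO10 than in AGO1 (4.49 to 4.78). It was only 1.03-fold lower relative to guide reads without miR165 and miR166, but 2.08-fold lower under median-of-ratios scaling. The reads of TAS1A and TAS1C, all shared with other places, were 11.3-fold lower (10.2 to 12.5) and 11.2-fold lower. The reads of TAS3B were 3.45-fold higher (2.92 to 4.06), but every one also matched TAS3A, so TAS3B is not a separate measurement. Summed over 8 loci, TAS reads were 1.27-fold higher in AGO10 than in AGO1 (1.26 to 1.29). TAS1A, TAS1C, TAS2, TAS3B and TAS3C lie outside the covered part and add only shared reads, so the sum mainly describes TAS3A and TAS1B. Without TAS3A the sum was at 0.210 of the AGO1 level (0.205 to 0.216), an alternative chosen after the data were seen. Relative to guide reads without miR165 and miR166 that value is multiplied by 4.47, and the full sum over 8 loci was 5.70-fold higher.

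Of 5 TAS loci with enough reads, only TAS3B, whose reads are shared with TAS3A, was at least 2-fold higher in AGO10 than in AGO1, and 3 were lower (median 4.63-fold lower, percentile 56.7). Relative to guide reads without miR165 and miR166, TAS3A and TAS3B were at least 2-fold higher, TAS1A and TAS1C lower, and TAS1B within 2-fold. Under median-of-ratios scaling TAS1B was at least 2-fold lower too. The lower TAS1A and TAS1C are not separate measurements, because 97.4% of AGO10 reads matching either matched both. Neither is separate from TAS1B: reads shared with TAS1A or TAS1C made up 20.8% of AGO10 reads matching TAS1B and 42.1% in AGO1. TAS1B also had single-match reads, 5274 in AGO10 and 10516 in AGO1. All 5 were higher in AGO1 than in total RNA (median 3.52-fold, percentile 33.4), though relative to guide reads without miR165 and miR166 all 5 ratios were below 1, with only TAS3B at least 2-fold lower, and 2 were higher and 2 lower in AGO10 than in total RNA (percentile 31.0). Single ta-siRNAs differed within 1 gene. Of the 2 listed TAS3 ta-siRNAs that target ARF mRNAs, the D7 form was 3.03-fold higher in AGO10 than in AGO1 (2.82 to 3.26). The D8 form was at 0.404 of the AGO1 level (0.352 to 0.463), a direction that flipped to 1.81 relative to guide reads without miR165 and miR166. Under median-of-ratios scaling, which multiplies these ratios by 2.22, the D8 form stayed lower in AGO10. The TAS1 ta-siRNA siR255, which matched 3 places, was at 0.0844 of the AGO1 level in the main scaling (0.0798 to 0.0893). The median of the 3 lay at percentile 68.3. All 3 were higher in AGO1 than in total RNA (percentile 28), and all 3 directions flipped relative to guide reads without miR165 and miR166. Against total RNA, AGO10 had 1 higher and 1 lower (percentile 45.1).

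**Figure D3:**
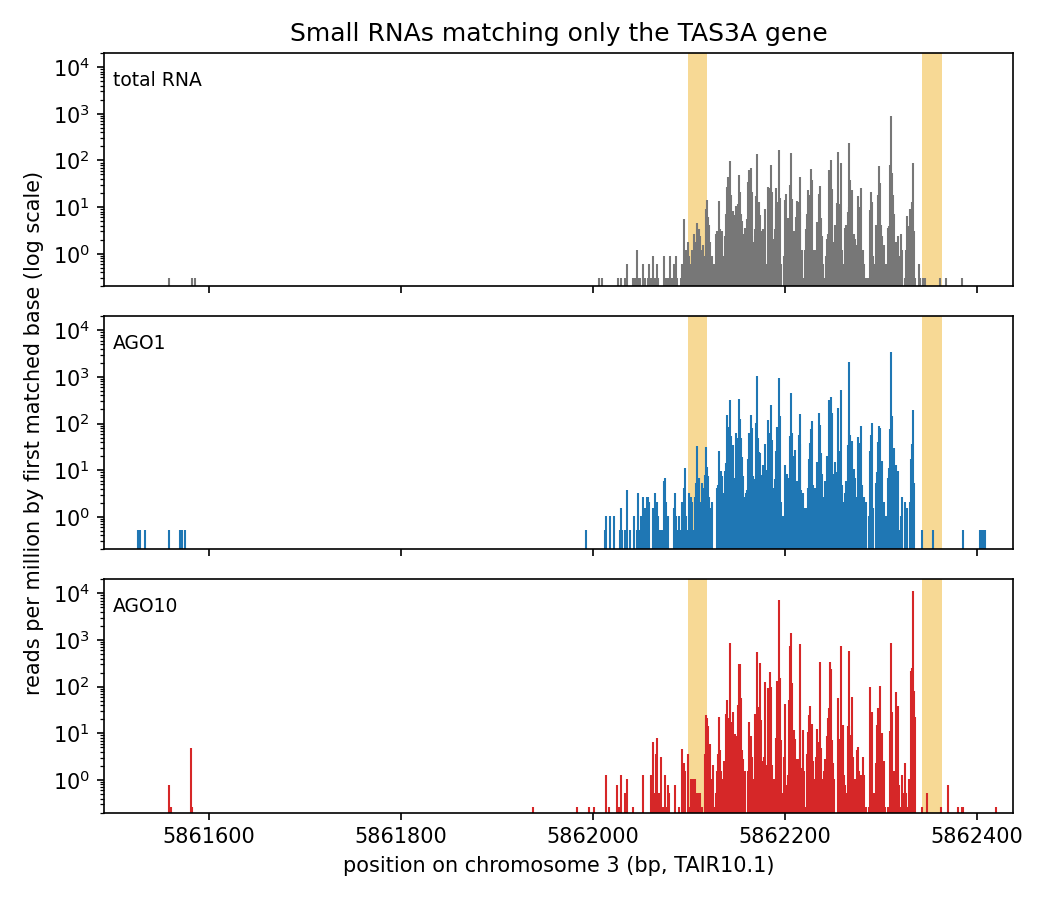
RPM (y axis, log scale) by the first matched base on chromosome 3 (x axis, bp, TAIR10.1) for reads that match only TAS3A, in total RNA, AGO1 and AGO10, 1 library each. Shaded bands mark the 2 closest matches to the miR390 complement, and the tallest AGO10 line, at 5862333, belongs to a sequence that ends inside the band on the right.

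At TAS3A the net AGO10 excess under the main scaling rested on 2 sequences, while reads at other starts differed in both directions. The sequence listed as GGGATAGACAAGGTAGGAGAA, on chromosome 3 from 5862333 to 5862353, stood at 9433 RPM in AGO10, 154 in AGO1 and 68.0 in total RNA, 61.4-fold higher in AGO10 than in AGO1 (54.7 to 69.1). A second, GGTCAAGAAAAGGCCTTACAA, from 5862194 to 5862214, stood at 6340, 851 and 143 RPM, 7.45-fold higher (7.08 to 7.84). Without both sequences, which were chosen after their values were seen, TAS3A reads were at 0.976 of the AGO1 level (0.962 to 0.990), a direction that flips when ratios are multiplied by the 4.47 of the scaling to guide reads without miR165 and miR166. The strand of origin of these reads was not analysed here. The leading TAS3A sequence of AGO1 and total RNA, from 5862310 to 5862330, was 3.86-fold lower in AGO10 than in AGO1 (3.70 to 4.03). This direction also flips relative to guide reads without miR165 and miR166, but not under median-of-ratios scaling.

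Of 180 annotated genes outside miRNA and structural RNA with at least 200 reads in AGO10 or AGO1, 4 were at least 2-fold higher in AGO10 and 164 at least 2-fold lower. Relative to guide reads without miR165 and miR166 the split was 17 and 8, and under median-of-ratios scaling 8 and 81. The AGO10 gene itself led, with 1148 reads in AGO10 and 3 in AGO1 (188-fold, 64.2 to 914). AGO2, a miR403 target, was 3.63-fold higher (2.72 to 5.02), and TAS3B, through reads shared with TAS3A, the pseudogene AT3G43828 (2.37-fold, 1.98 to 2.84) and TAS3A itself followed. The lowest were the pseudogene PSEUDOSRKA, AT4G21370 (12-fold lower, 11.1 to 13), AT4G08990 (11.9-fold, 8.74 to 16.1), TAS1A and TAS1C, both through shared reads, and the long non-coding RNA AT3G07855 (10.2-fold, 8.94 to 11.7). The AGO1 gene, AT1G48410, had 397 reads in AGO1, 147 in AGO10 and 80 in total RNA, 5.49-fold lower in AGO10 than in AGO1 (4.53 to 6.68). It was only 1.23-fold lower relative to guide reads without miR165 and miR166, but 2.47-fold lower under median-of-ratios scaling. The median of the AGO1 and AGO10 genes lay at percentile 100 for AGO10 against AGO1 and 0 for AGO1 against total RNA, and describes neither gene because they differed in opposite directions. Against total RNA, both were higher in AGO10, by 1.59-fold for AGO1 (1.2 to 2.11) and 1.99-fold for AGO10 (1.79 to 2.21, and 2.16-fold per listed read), so neither reached 2-fold under the main scaling (percentile 68.8).

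Few reads came from HD-ZIP III genes, the targets of miR165 and miR166. None of the 5 reached 100 reads in any library. PHV stood at 4.55 RPM in AGO10, 5.81 in AGO1 and 1.35 in total RNA, and ATHB15 at 2.34, 5.81 and 3.61. PHB, REV and ATHB8 lie outside the part of the genome for which reads of single-copy sequence outside hairpins were analysed here.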

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

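The tests in this part were all chosen after the result was seen. Reads matching the AGO10 gene, AT5G43810 on chromosome 5 from 17610744 to 17616907, stood out because they lie outside the miRNA measurement and exceed what a library with 0 true reads would give. Single-match reads numbered 1148 in the AGO10 library, 499 in total RNA and 3 in AGO1. They came from 632 distinct sequences in AGO10 and 466 in total RNA, of which 78 were shared, and no sequence had more than 22 reads. Annotated exons, which cover 68.6% of the gene, held 98.4% of these reads in AGO10 (97.5% to 99.1%) and 97.4% in total RNA (95.6% to 98.6%).

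Several technical explanations were weighed. Breakdown products of AGO10 mRNA would spread over lengths as structural RNA fragments do, but 82.8% of the AGO10 gene reads in total RNA were 21 or 22 nt (79.2% to 86.0%), against 25.8% of structural reads in that library. Leakage of AGO10 library reads into the total RNA library would have to carry 43.5% of the reads, while miR165 and miR166 reads in total RNA were only 0.762% of those in AGO10. Both tests argue against these explanations as the whole source. A candidate explanation that stays open is small RNA production from the tagged transgene in each line: AGO1 gene reads were 5.49-fold higher in the AGO1 library than in the AGO10 library (4.53 to 6.68), though only 1.23-fold relative to guide reads without miR165 and miR166 and 2.47-fold under median-of-ratios scaling. It also predicts at most 3 AGO10 gene reads in total RNA if those plants lacked the AGO10 transgene. Total RNA had 499, but the labels do not say which plants gave it, so that count decides nothing. Plant line and purified protein cannot be told apart here.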

How the results depend on the processing

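No paired analysis was possible because each group had 1 library. The direction held for miR165 and miR166 in every scaling and counting tried, for which the AGO10 to AGO1 ratio ranged from 9.56 to 42.8. Changes outside the narrow counting intervals follow; unless a cause is named, the cause was not tested. Alternatives marked by an asterisk were chosen after seeing the data.

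With all listed reads, with reads without structural RNA, with guide reads other than miR165 and miR166, and under median-of-ratios scaling, the miR165 and miR166 ratio was 9.90, 9.67, 42.8 and 21.3 for AGO10 over AGO1, 12.5, 10.5, 1.98 and 3.47 for AGO1 over total RNA*, and 124, 101, 84.5 and 73.7 for AGO10 over total RNA*. The TAS sum was 1.32, 1.29, 5.70 and 2.83. The star sum was 1.31 with the other guide reads, a reversal, and 0.653 under median of ratios. These last 2 scalings shift every AGO10 over AGO1 ratio by one factor, 2.16 and 1.15 in log2, which is the cause. Entries higher and lower were 22 and 22, and 16 and 27, for AGO10 against AGO1, and 13 and 17, and 18 and 4 (miR390, miR394, miR170 and miR391), for AGO1 against total RNA. Other genes higher and lower in AGO10 than in AGO1 were 17 and 8, and 8 and 81, chosen later too.

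With the full mature sequence alone, the ratios were 12.1* for AGO1 and 116* for AGO10 over total RNA, and the miR165 and miR166 share of miRNA reads was 89.9% in AGO10, 15.2% in AGO1 and 8.33% in total RNA. Minimums of 20 reads and of 1 read each gave 1 lower entry in AGO1 against total RNA, miR861-3p. Entries from the annotated mature miRNAs of the reference*, both arms and more of them, gave 13 higher and 65 lower for AGO10 against AGO1, 76 and 13 for AGO1 against total RNA, and 43 lower for AGO10 against total RNA.

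In total RNA, AGO1 and AGO10, the 21-nt share was 7.77%, 23.9% and 24.3% over distinct sequences, 11.6%, 47.8% and 75.8% over all listed reads, and 11.8%, 49.5% and 79.6% without structural RNA. The 5′ U share was 45.7%, 61.0% and 67.6% over distinct sequences and 54.3%, 79.5% and 92.7% over all listed reads, where minus-strand listing fixes part of the bases. The structural share was 4.09%, 1.67% and 5.77% over distinct sequences and 6.74%, 0.944% and 0.908% with annotated genes alone*. The TAS sum was 1.48 with single matches, 1.25 with 21-nt reads and 0.210 without TAS3A*, a reversal because TAS3A holds most TAS reads. The star sum was 0.169 without miR171a*, also chosen after seeing the data. The star share of star and guide reads without miR165 and miR166, another later choice, was 3.50%, 0.607% and 1.08%, because guide reads of that family fill most of the AGO10 total.

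Limiting isoforms to genome-matched reads, or structural RNA to all lengths, moved nothing because all listed sequences match the genome and lie within the lengths used. Leaving out structural RNA did not move the 5′ U share because hairpin reads hold none.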

Other observations

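Members of 1 miRNA family that share their first 18 nt were carried in different proportions. MiR159b, which differs from miR159a by A21U counted from the 5′ end, made up 82.4% of exact miR159a and miR159b reads in AGO10 (82.0% to 82.8%), 28.8% in AGO1 (28.6% to 28.9%) and 37.0% in total RNA (36.5% to 37.5%). MiR396a, which differs from miR396b by U21G, made up 78.9% of that pair in AGO10 (78.3% to 79.6%), 17.0% in AGO1 (16.5% to 17.4%) and 11.8% in total RNA (11.3% to 12.3%). The 22-nt miR167d made up 41.2% of reads with miR167a and b in AGO10, 3.11% in AGO1 and 2.15% in total RNA. By contrast, miR172c and d, which differ from miR172a and b by U21G, made up 36.0%, 25.6% and 34.3% of their pair. These shares do not depend on the scaling. The genes were chosen after their values were seen.

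Star strands also differed by family. MiR171a* made up 30.3% of star and guide reads of its family in AGO1 (29.3% to 31.4%), 12.4% in total RNA (11.3% to 13.5%) and 2.33% in AGO10 (2.22% to 2.44%). The guides of that family include miR171b and c, which have no listed star strand. These held 27463 of 71059 guide reads in AGO10 and 2380 of 5181 in AGO1. MiR168* made up 40.6% in AGO10 (36.5% to 44.8%), 48.8% in total RNA (46.9% to 50.7%) and 1.64% in AGO1 (1.19% to 2.20%). MiR408* made up 19.7% in AGO1 (18.4% to 21.1%).

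The tests in the next paragraphs were all chosen after the results were seen. The first pattern is that 36 guide entries other than miR165 and miR166 were at least 2-fold lower in AGO10 than in AGO1. One explanation is that miR165 and miR166 took most AGO10 reads and so lowered the level of everything else. Relative to guide reads without miR165 and miR166, 14 of these entries were no longer 2-fold lower. For 11 of them the counting interval then reached equality or lay on the higher side. This scaling also takes out any lower share of other guides among the remaining reads. It therefore cannot show that the explanation accounts for the whole difference of these 11. The other 3 stayed lower by less than 2-fold with an interval that excluded equality, so the explanation does not cover their whole difference. These were miR827, from 8.38-fold lower (7.30 to 9.64) to 1.87-fold (1.63 to 2.16), miR167a-b/d, from 5.31-fold (5.14 to 5.48) to 1.19-fold (1.15 to 1.22), and miR860, from 6.46-fold (4.48 to 9.52) to 1.45-fold, whose interval of 1.00 to 2.13 only just did so. The miR167a-b/d entry pools members that differed in direction. Exact miR167a and b stood at 682 RPM in AGO10 and 5998 in AGO1, and miR167d at 477 and 192. For 22 entries, miR397a, miR408, miR164 and miR172 among them, the explanation does not account for the whole difference, because they stayed at least 2-fold lower. Carry-over of unbound RNA, if it gave nearly all the other AGO10 miRNA reads, would make them mirror total RNA. Only 22.2% of 45 entries lay within 2-fold of their median AGO10 to total RNA ratio. This argues against carry-over as nearly the whole source only if total RNA resembles the extract used for AGO10. The labels do not say which plants gave total RNA. A smaller carry-over would pass unseen in this test and stays open. A difference between the proteins in binding or in the cells that express them also stays open and was not tested. Plant line and purified protein cannot be told apart for this pattern either.

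The second pattern is the AGO10 excess of 2 TAS3A sequences. If PCR had amplified single molecules, neighbouring sequences that share only 1 end would not follow. They were 32.8-fold higher in AGO10 at the first site (27.3 to 39.9) and 6.90-fold higher at the second (6.02 to 7.94). This argues against that explanation only if the neighbours were separate molecules, because copies shortened after amplification would follow too. At the first site 5740 of the 7614 neighbour reads in AGO10 were 1 sequence, 1 nt shorter. Each sequence matched 1 place in the genome, so reads shared with another locus do not account for it either. The first sequence ends at 5862353, exactly the last base before the expected cut between miR390 bases 10 and 11 at the nearer of 2 sites, which spans 5862343 to 5862363. Each site has 5 mismatches to the full miR390 complement. No biological explanation was tested.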
